A study of Mus musculus with 16 samples.

How the data were processed

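C2C12 cells, an established mouse myoblast line that fuses into contractile myotubes, were differentiated for 5 days and then left unstimulated (control) or given electrical pulse stimulation (EPS), in which an electric field is applied to the culture. Per the labels, pulses of 6 ms came at 1 Hz with a field of 2.75 V/mm and a duty cycle of 0.6%, and the polarity was switched at 0.5 Hz. The length of the stimulation is not given in the sources used here. Cellular RNA was extracted with a kit and made into libraries with a stranded kit for total RNA, per the labels' protocols. The 16 GEO samples are 8 libraries with 2 lanes each, 4 control and 4 EPS, and the deposited table holds 1 value per gene and library. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

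The submitters' processing notes name STAR 2.5.1, Cufflinks, Cuffdiff 2.2.1 and the mouse genome build mm10. Per the file headers, the deposited table is Cuffdiff's output per gene and replicate, with a column of estimated counts (fragments per gene, not scaled) and a column of FPKM. The strand setting of the counting and the annotation release are not given in the sources used here. Of the estimated counts above 0, 93.3% were exactly whole, and all were rounded to whole numbers before testing. The FPKM values, as deposited, are fragments per kilobase and M fragments after Cuffdiff's scaling between libraries, and they served only for an alternative test.

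The table lists 48432 gene identifiers. Symbols, positions, transcript lengths and GC contents came from a GENCODE annotation of the same genome build, matched on the identifier without its version, and 48051 identifiers had a symbol. In 46 genes the table marks the estimate as skipped because of too many fragments (40 in control, 15 in EPS, 9 in both), with 0 in place of an estimate, so these genes were left out of library sizes and tests. Another 9 genes had a failed FPKM estimate in at least 1 library and kept their fragment counts. The 15 genes of the mitochondrial genome are listed at 0 in every library and were not tested.

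Control libraries 1 to 4 held 18.6, 0.354, 12.6 and 20.7 M fragments (M, 10 to the power of 6), and EPS libraries 1 to 4 held 20.1, 14.7, 18.1 and 20.7 M. These totals cover all listed genes, including those marked as skipped in 1 group only, which were left out of the library sizes used in tests. A count of 3 fragments, taken as the limit that a count of 0 allows, corresponds to 0.146 to 0.239 CPM in the 7 deep libraries and to 8.68 CPM in control replicate 2. Limits cover counting error only, and bootstrap intervals cover only the choice of genes in a list.

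Genes were filtered with filterByExpr by group (a minimum count of 10 and a minimum total of 15), scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on all 8 libraries with no covariate. The threshold was an adjusted p of 0.05 (Benjamini-Hochberg over the 13987 genes tested). Fold changes are edgeR's fitted values and need not equal the ratio of the mean CPM values printed beside them. Standard errors of log2 fold changes were derived from the fold change and its F statistic and are approximate. CPM values use TMM-scaled library sizes, and log2 CPM values have a prior count of 2. On counts simulated from these libraries (13459 genes), the test recovered 37 of 100 genes changed by 2-fold and 86 of 100 changed by 4-fold, with 16 unchanged genes called. The share of unchanged genes among the calls was thus above the 0.05 that the threshold aims at. The simulated libraries were drawn independently, without the pairing by replicate number seen in the data (below), so these rates need not hold for the real libraries.

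Before the data were examined, 37 gene lists were fixed for muscle, stress, metabolism, other cell types and RNA quality. The 33 lists with at least 5 tested members were compared with all other tested genes by camera on log2 CPM with a preset correlation of 0.01, adjusted over lists, and again with a correlation estimated per list. Fry asked a different question, whether the genes of a list move on balance in 1 direction, with no comparison to other genes. The rule for named genes, also fixed then, takes Gdf15; the 10 highest and 10 lowest fold changes among genes past the threshold with a mean CPM of at least 5, an ordinary gene symbol and no overlap of the groups; and from each list up to 4 called members with the smallest adjusted p, or its most abundant member where none was called. The text leaves out 12 uncalled genes of the last kind. Members of 6 further lists in the closing section were chosen after values were seen.

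Control and EPS libraries share the replicate numbers 1 to 4, with no statement of what a number marks. Across genes, deviations from the group mean correlated between libraries of the same number with coefficients of 0.300, 0.214, 0.286 and 0.297, and each library correlated best with its own number in the other group. Between different numbers, coefficients were nearly as high for control 3 with EPS 4 (0.231) and control 4 with EPS 3 (0.253). They were 0 for control 1 with EPS 2 and 0.006 for control 2, the shallow library, with EPS 1. The numbers therefore pair the libraries in part, with replicates 3 and 4 hardly told apart. A fit with the replicate number as a block was chosen beforehand as a second test.

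Alternatives fixed beforehand were other scalings, other filters, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1 and 0.1, the replicate block, a test against a 1.2-fold change and leaving out each library in turn. Added after seeing the data were robust dispersion estimates, library weights, the block without pair 2, loess offsets for transcript length and GC, and a batch of replicates 1 and 2 against replicates 3 and 4. The labels name no batch; that division was seen in principal components and list medians, and it runs across both groups.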

Results

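The transcriptome of C2C12 myotubes was measured by RNA sequencing with and without electrical pulse stimulation, in 4 control and 4 EPS libraries. The series title concerns secretion of GDF15, a stress-responsive cytokine of the TGF-beta superfamily, after muscle contraction, so the comparison asks which transcripts, Gdf15 among them, differ in stimulated myotubes. The 7 deep libraries held 12.6 to 20.7 M fragments and control replicate 2 held 0.354 M. Without the skipped genes, mean depth was 12.9 M ± 9.05 (SD, n = 4) in control and 18.3 M ± 2.66 (SD, n = 4) in EPS. This difference lay within the spread of libraries (exact two-sided permutation p = 0.371, smallest possible 0.0286). The first principal component of log2 CPM (68.4% of the variance) set control replicate 2 apart, and on the second (20.2%) EPS replicates 1 and 2 lay at 46.4 and 88.1, with the other libraries between -45.25 and 1.63.

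Gdf15 rose in EPS myotubes. Its level was 3.76 CPM ± 1.36 (SD, n = 4) in control and 44.5 CPM ± 28.5 (SD, n = 4) in EPS, and the fold change fitted by edgeR was 14.0 (log2 fold change 3.80, SE 0.48, adjusted p = 0.00304). Each of the 4 EPS libraries (47.2, 83.7, 23.8 and 23.2 CPM) lay above each of the 4 control libraries (3.09, 5.68, 3.70 and 2.58 CPM). The gene (ENSMUSG00000038508) lies on chromosome 8 of mm10, positions 70629393 to 70632456, on the minus strand. Within replicates 1 and 2 the log2 fold change was 4.35 (SE 0.41), and within replicates 3 and 4 it was 2.93 (SE 0.32), a difference that did not pass its own test (adjusted p = 0.401). That test passed no gene at all, so this does not show that the sets agree. The control value of replicate 2 rests on 2 fragments. The call was lost in limma on log2(FPKM + 0.1), where the log2 difference was 3.19 (adjusted p = 0.0545).

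Across the transcriptome, the main fit called more genes higher than lower in EPS. Of 13987 genes tested, 322 were higher and 106 lower in EPS, and 279 and 72 of these differed by 2-fold or more. Higher genes made up 75.2% of these calls and 80.4% in replicates 1 and 2 alone. They made up only 50.8% in replicates 3 and 4 alone and 52.5% with the block without pair 2. The size of the excess thus depends on the fit and the libraries. The largest increases among genes named by the rule were in detoxification enzymes, inducible heat shock proteins and stress genes. Cyp1a1, a cytochrome P450 that oxidises aromatic compounds, had no fragments in any control library and 30.3 CPM ± 11.9 (SD, n = 4) in EPS, at least 534.1-fold higher against a floor of 3 fragments over the control group. Hspa1a and Hspa1b, which encode inducible HSP70, had log2 fold changes of 7.63 (SE 1.06) and 6.71 (SE 0.88), with 8.63 and 7.40 within replicates 1 and 2 and 4.87 and 4.798 within replicates 3 and 4. With the block these were 6.12 and 5.78, and without EPS replicate 2 they were 6.60 and 5.77, so the order among these genes depends on the fit. The glutathione transferases Gsta2 and Gsta1 had 6.84 (SE 0.36) and 6.47 (SE 0.44), and the aldehyde dehydrogenase Aldh3a1 had 6.39 (SE 0.30). The cystine transporter Slc7a11, the stress transcription factor Atf3, heme oxygenase Hmox1 and the quinone reductase Nqo1 followed with 6.25, 6.12, 5.58 and 5.33. Atf3 was at 5.32 with the block and 5.35 without EPS replicate 2, and Gsta1 at 7.38 without control replicate 1. The pairs Hspa1a and Hspa1b and Gsta1 and Gsta2 are near-identical copies, so the share of each within its pair is uncertain.

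The largest decreases among genes named by the rule were smaller. Nmrk2, a muscle nicotinamide riboside kinase, was at 11.4 CPM ± 5.82 (SD, n = 4) in control and 2.10 CPM ± 1.05 (SD, n = 4) in EPS, a log2 fold change of -2.16 (SE 0.42). The myosin heavy chain Myh7b had -2.03 (SE 0.31), the sodium channel Scn7a -1.96 and Fst, which encodes the activin and myostatin antagonist follistatin, -1.95 (SE 0.26). Fst went from 392 CPM ± 38.6 (SD, n = 4) in control to 101 CPM ± 39.0 (SD, n = 4) in EPS. Fam107a, Gpr20, Trp63, Ablim3, Otog and Mss51 had log2 fold changes between -1.86 and -1.53. Nmrk2 and Myh7b overlap other tested genes on the opposite strand (Atcayos and Trpc4ap, adjusted p = 0.983 and 0.872), so fragments there cannot be assigned with certainty. The same limit applies below to Sqstm1 (Mrnip), Fosl1 (Ccdc85b), Ccnd1 (LTO1) and Cryab (Hspb2), with adjusted p of 0.673, 0.756, 0.689 and 0.335 for the overlapping genes. Nmrk2 and Mss51 were no longer past the threshold without control replicate 1, 3 or 4 or EPS replicate 1 (highest adjusted p 0.0982 and 0.0736). The same held for Fam107a without control replicate 1, 3 or 4 (0.0837), Gpr20 without control replicate 1 or 3 or EPS replicate 1 (0.0816) and Scn7a without control replicate 1 (0.0540).

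**Figure D1:**
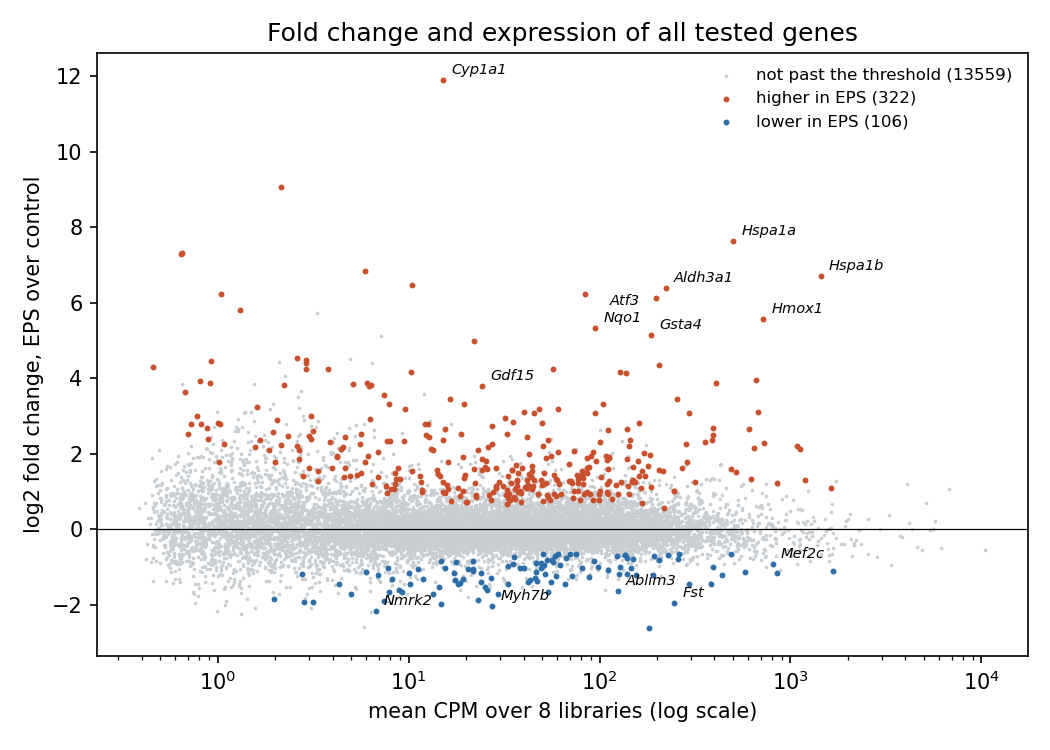
Log2 fold change of EPS over control against mean CPM over the 8 libraries (log scale) for the 13987 tested genes, with 322 higher and 106 lower genes in colour and examples named. The fitted value of Cyp1a1, which had no control fragments, depends on the prior count and is not a bound.

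At an unadjusted p under 0.05 there were 2590 genes. The groups did not overlap in 314 of the 322 higher and 100 of the 106 lower genes; chance gives this in 2.86% of genes, and it was seen in 14.2% of all tested genes. With the replicate number as a block, 1023 genes were higher and 668 lower, including all 322 and all 106. Leaving out control replicate 1, 3 or 4 or EPS replicate 1 reduced the higher genes to 98, 92, 94 and 111 and the lower genes to 22, 27, 36 and 28. Without the shallow control replicate 2 there were 283 higher and 167 lower genes. A fit that pools the spread of all libraries called 1191 higher and 575 lower genes within replicates 1 and 2, and 153 and 41 within replicates 3 and 4. Separate fits reversed this order, with 510 and 124 in replicates 1 and 2 alone and 1156 and 1121 in replicates 3 and 4 alone, so these counts do not rank the response of the 2 sets. All 428 called genes had the same direction in both sets by the pooled fit, where 402 were past the threshold in replicates 1 and 2, and 176 in replicates 3 and 4. In the separate fits 196 higher and 49 lower of them were past it in replicates 1 and 2, and 319 and 106 in replicates 3 and 4. No gene passed edgeR's test of the difference between the 2 sets of replicates (0 of 13987), with 1483 at an unadjusted p under 0.05, more than chance gives. Hspa1a did not pass it with a difference in log2 fold change of -3.76 (SE 0.57, adjusted p = 0.383). The lack of calls therefore does not show that the sets agree.

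Targets of NRF2, the transcription factor of the antioxidant response, rose together. Of 30 tested members, 24 rose and 6 did not pass the test (27 higher adjusted over the list alone), with a median log2 fold change of 1.67. Nqo1 went from 4.85 CPM ± 1.14 (SD, n = 4) to 184 CPM ± 24.8 (SD, n = 4), and Hmox1 from 27.4 CPM ± 10.0 (SD, n = 4) to 1411 CPM ± 630 (SD, n = 4). Gsta4, a glutathione transferase for lipid peroxidation products, had a log2 fold change of 5.14 (SE 0.22), and Srxn1, which repairs oxidised peroxiredoxins, 4.18 (SE 0.31). The list was higher than other genes by camera (adjusted p = 7.96e-29), and it was the only one of the 33 lists whose call held with an estimated correlation (adjusted p = 0.00794). Its median differed little between replicates 1 and 2 (1.63) and replicates 3 and 4 (1.57), and 19 to 25 members were called when any 1 library was left out.

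Heat shock chaperones controlled by HSF1 also rose. Of 22 tested members, 11 rose and 11 did not pass the test (20 higher adjusted over the list alone, 20 with the replicate block), with a median log2 fold change of 1.36. Hspa1b went from 31.2 CPM ± 15.2 (SD, n = 4) to 2844 CPM ± 3001 (SD, n = 4). The co-chaperone Dnajb1 and the small heat shock protein Hspb1 had log2 fold changes of 3.88 (SE 0.60; 3.28 without EPS replicate 2) and 2.65 (SE 0.35). The camera call (adjusted p = 1.77e-11) was lost with an estimated correlation (adjusted p = 0.272 with an estimated correlation). EPS libraries 1 to 4 had list medians of 1.56, 2.19, 0.74 and 0.67 relative to the control mean, and control libraries lay between -0.14 and 0.22. The median was 1.81 within replicates 1 and 2 and 0.72 within replicates 3 and 4. Camera on the difference gave an adjusted p of 7.28e-08, and 0.454 with an estimated correlation. Here and in later comparisons of the sets, camera counts the shallow control replicate 2 as much as control replicate 1. Within replicates 1 and 2, the control side thus has only 1 deep library. Members called fell to 5, 5, 4 and 4 without control replicate 1, 2, 3 or 4 and to 4 without EPS replicate 1.

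Target genes of the integrated stress response, driven by ATF4 and CHOP, rose in part. Of 43 tested members, 11 rose and 32 did not pass the test (25 higher adjusted over the list alone, 21 with the replicate block), and 39 had a positive fold change. Atf3 went from 8.06 CPM ± 6.23 (SD, n = 4) to 386 CPM ± 358 (SD, n = 4), Trib3, a pseudokinase induced by CHOP, had a log2 fold change of 3.31 (SE 0.42), and Gdf15 and Slc7a11 are also members. The list had an adjusted p of 1.18e-12 by camera and of 0.233 with an estimated correlation. Medians were 0.81 within replicates 1 and 2 and 0.58 within replicates 3 and 4. Chaperones and degradation factors of the endoplasmic reticulum, under ATF6 and XBP1, had no called member by edgeR among 24 tested (2 at an unadjusted p under 0.05, 1 by DESeq2, 2 with the replicate block; list adjusted p = 0.404).

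**Figure D2:**
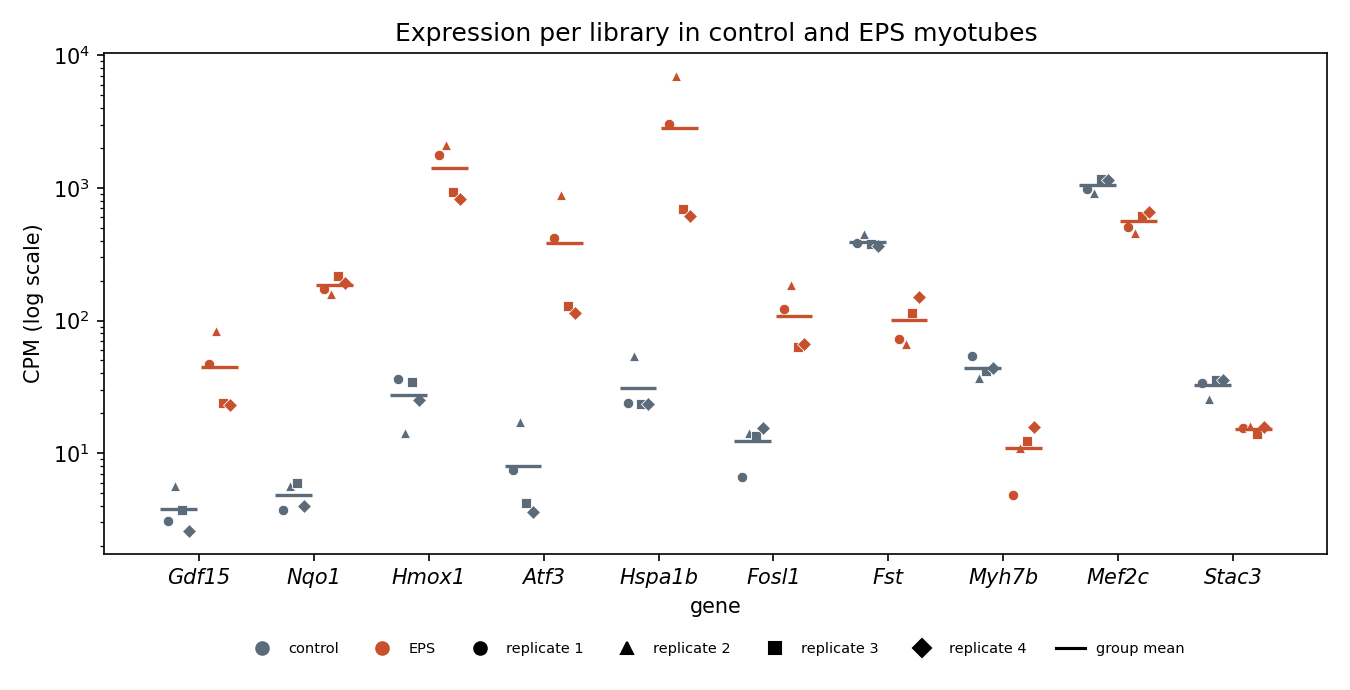
CPM (log scale) of 10 genes in each of the 4 control and 4 EPS libraries, with marker shapes for replicate numbers and a line at each group mean. EPS values of Gdf15 lie between 23.2 and 83.7 CPM, all above the control values, and those of Fst, Myh7b, Mef2c and Stac3 lie below theirs.

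Immediate-early genes, which respond to stimulation and calcium entry, and inflammatory genes contained further increases. Of 31 immediate-early genes, 5 rose and 26 did not pass (16 higher and 1 lower adjusted over the list alone; 14 higher and 3 lower with the replicate block). Fosl1, an AP-1 subunit, went from 12.4 CPM ± 3.98 (SD, n = 4) to 109 CPM ± 57.1 (SD, n = 4), and Arc, an activity-regulated gene best known from neurons, had a log2 fold change of 3.45 (SE 0.52; 2.86 without EPS replicate 2). The list median was 1.22 within replicates 1 and 2 and 0.24 within replicates 3 and 4 (camera on the difference, adjusted p = 8.13e-08, and 0.454 with an estimated correlation). Relative to the control mean, control replicate 1 and the shallow control replicate 2 were themselves at 0.251 and -0.493. Of 21 NF-kB targets, 6 rose and 15 did not pass (10 higher and 1 lower adjusted over the list alone), among them the chemokine Cxcl5 (log2 fold change 3.00, SE 0.41) at a low level of 1.42 CPM ± 0.0988 (SD, n = 4) in EPS. Camera gave adjusted p = 0.000472 for immediate-early genes and 0.000413 for NF-kB targets, and 0.509 and 0.271 with an estimated correlation. Immediate-early calls fell to 2 and NF-kB calls to 1 without control replicate 1, 3 or 4; without EPS replicate 1 both were at 2, and NF-kB calls were at 3 without control replicate 2. Immediate-early calls were 8 and 9 without EPS replicate 3 or 4.

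FoxO targets and autophagy genes, p53 targets and factors secreted by muscle had smaller sets of called members. Of 25 FoxO and autophagy genes, 5 rose and 20 did not pass (10 higher adjusted over the list alone; 9 higher and 1 lower with the block; list adjusted p = 0.00119, and 0.372 with an estimated correlation). The autophagy receptor Sqstm1, also an NRF2 target, went from 414 CPM ± 59.5 (SD, n = 4) to 1828 CPM ± 714 (SD, n = 4). FoxO and autophagy calls fell to 1, 2 and 3 without control replicate 1, 3 or 4 and to 3 without EPS replicate 1, and were 8 without EPS replicate 3. The median of that list was 0.53 within replicates 1 and 2 and 0.20 within replicates 3 and 4. Camera on the difference gave an adjusted p of 0.00422, and 0.454 with an estimated correlation. Of 26 p53 targets, 2 rose, Gdf15 and Sesn2, an inhibitor of mTORC1 (8 higher and 2 lower adjusted over the list alone; 8 higher and 1 lower with the block). Both are also members of the integrated stress response list. The p53 list had an adjusted p of 0.0512, and it passed the threshold with the block (adjusted p = 0.0219), with limma on log2(FPKM + 1) (0.0213) and without control replicate 2 or EPS replicate 3 or 4 (0.0256, 0.0175 and 0.0258). Sesn2 was not past it without EPS replicate 1 or any 1 control library (highest adjusted p 0.127), and p53 calls were at 4 and 5 without EPS replicate 3 or 4. Of 37 factors reported to be secreted by muscle, 4 rose, among them Gdf15 and Cxcl5, and Fst fell (4 and 1 adjusted over the list alone; 4 and 8 with the block). The median of that list was -0.07, its mean 0.11, and its list test was not past the threshold (adjusted p = 0.804); its higher genes were 2 without any 1 control library or EPS replicate 1.

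Genes of the contractile apparatus were lower on average in EPS, with few single genes past the threshold over all genes. Of 18 fast-fibre genes, 1 fell, Mybpc2, which encodes fast myosin-binding protein C (14 lower adjusted over the list alone, 13 with the replicate block), and the median log2 fold change was -0.76. Of 14 slow-fibre genes, 1 fell, Myh7b, from 43.9 CPM ± 6.98 (SD, n = 4) to 10.98 CPM ± 4.56 (SD, n = 4) (4 lower adjusted over the list alone, 7 with the block; median -0.61). Of 9 contractile genes of developing muscle, edgeR called 0 over all genes (4 at an unadjusted p under 0.05, 2 by DESeq2), 2 were lower adjusted over the list alone and 6 with the block. Embryonic myosin Myh3 had a log2 fold change of -0.50 (adjusted p = 0.214, and 0.0388 with the block). Camera gave adjusted p = 1.86e-09, 2.89e-06 and 0.000113 for these 3 lists, and 0.200, 0.130 and 0.0787 with an estimated correlation. The fast-fibre median was -0.98 within replicates 1 and 2 and -0.50 within replicates 3 and 4, and the slow-fibre median was -1.04 and -0.40. Length and GC offsets narrowed this gap. Relative to the control mean, fast-fibre medians of EPS libraries 1 to 4 went from -0.805, -1.317, -0.415 and -0.426 to -0.679, -0.942, -0.559 and -0.564. Slow-fibre medians went from -0.876, -1.349, -0.408 and -0.248 to -0.65, -0.897, -0.581 and -0.358. Log2 CPM deviations correlated with log2 transcript length at 0.402, 0.416, -0.476 and -0.4 in EPS libraries 1 to 4. Without control replicate 2, 2 fast-fibre genes and 1 developmental gene were lower, and 2 slow-fibre genes were lower without EPS replicate 3 or 4. Mybpc2 was no longer past the threshold without control replicate 1, 3 or 4 or EPS replicate 1 (highest adjusted p 0.140).

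Regulators of muscle differentiation and proteins of excitation-contraction coupling were also lower on average. Of 15 myogenic regulators, 1 fell, the transcription factor Mef2c, from 1052 CPM ± 124 (SD, n = 4) to 561 CPM ± 93.8 (SD, n = 4) (4 lower adjusted over the list alone, 5 with the block). Of 25 coupling and triad genes, 1 fell, Stac3, an adaptor of the voltage-gated calcium channel, from 32.8 CPM ± 4.87 (SD, n = 4) to 15.3 CPM ± 0.972 (SD, n = 4) (1 adjusted over the list alone, 3 with the block). Of 32 structural sarcomere genes, Cryab, a small heat shock protein of the Z disc, rose and Klhl41 fell (5 higher and 9 lower adjusted over the list alone; 6 and 10 with the block). Of 19 genes held low by electrical activity, edgeR called 0 (2 higher and 6 lower at an unadjusted p under 0.05; 1 and 2 by DESeq2; 1 and 1 adjusted over the list alone; 1 and 6 with the block). The acetylcholine receptor subunit Chrna1 had a log2 fold change of -0.41 (adjusted p = 0.232). These 4 lists were lower by camera (adjusted p = 4.88e-05, 0.000764, 0.00921 and 0.0313), and with an estimated correlation the adjusted p was 0.130, 0.233, 0.3998 and 0.272. Mef2c and Klhl41 lost the call without control replicate 1, 3 or 4 or EPS replicate 1, Klhl41 also without EPS replicate 2, 3 or 4, and Cryab without control replicate 3 or 4 or EPS replicate 1 (highest adjusted p 0.127, 0.143 and 0.111). The list calls of structural sarcomere genes and of genes held low by activity were lost without control replicate 1 (adjusted p = 0.0616 for both) or EPS replicate 3 (0.0643 for both), and the latter also without EPS replicate 4 (0.0733). Without control replicate 2, 3 myogenic regulators and 4 structural genes were lower; without EPS replicate 3 or 4, 2 and 3 myogenic regulators were lower and 2 structural genes higher.

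**Figure D3:**
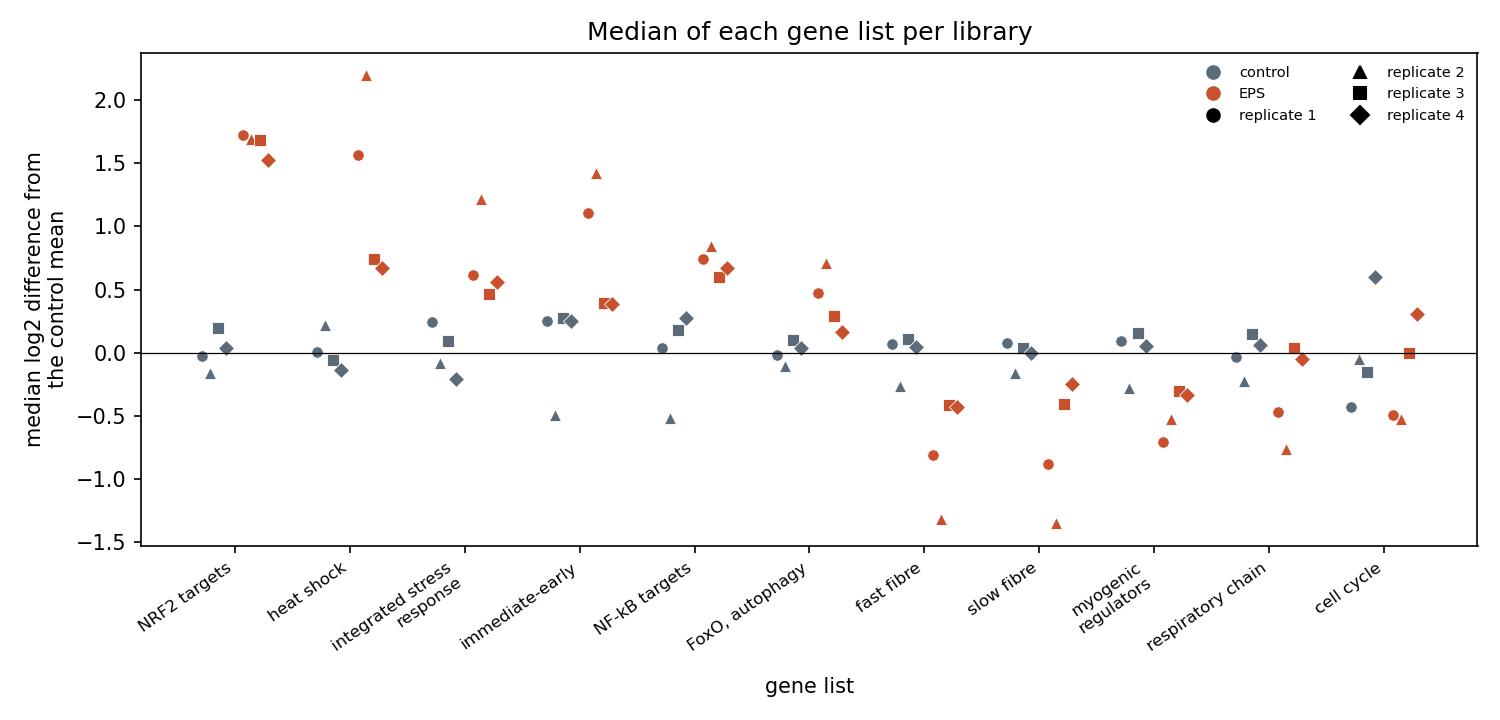
Median log2 difference from the control mean of the tested members of 11 gene lists, per library, with marker shapes for replicate numbers. EPS medians of NRF2 targets lie between 1.53 and 1.72, and those of heat shock genes between 0.67 and 2.19.

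Nuclear genes of the respiratory chain were slightly lower on average. Relative to the control mean, list medians of EPS libraries 1 to 4 were -0.469, -0.763, 0.039 and -0.048. Control libraries lay between -0.222 and 0.145, so only EPS libraries 1 and 2 were below their range. List members moved together (estimated correlation 0.540), so they are not separate observations. Of 75 tested, 2 had a positive fold change and the median log2 fold change was -0.31; edgeR called 0 (11 lower at an unadjusted p under 0.05, 0 by DESeq2, 2 lower with the block, 0 adjusted over the list alone). Atp5b, the catalytic subunit of ATP synthase, had a log2 fold change of -0.21 (adjusted p = 0.625). The median was -0.57 within replicates 1 and 2 and -0.13 within replicates 3 and 4 (camera on the difference, adjusted p = 1.64e-11, and 0.454 with an estimated correlation). After offsets for transcript length and GC, the median of the respiratory chain list over all libraries was -0.20. Of 19 tricarboxylic acid cycle genes, edgeR called 0 (3 lower at an unadjusted p under 0.05, 1 by DESeq2), with a median of -0.23. Of 25 cholesterol synthesis genes, edgeR called 0 (6 lower at an unadjusted p under 0.05, 1 by DESeq2, 6 with the block), and Hmgcs1, HMG-CoA synthase, was at -0.47 (adjusted p = 0.15, and 0.0354 with the block). Camera gave adjusted p = 6.72e-11, 0.000141 and 0.000733 for these lists, and 0.456, 0.130 and 0.452 with an estimated correlation. Adjusted over the list alone, neither of the last 2 lists had a called member.

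Other metabolic and regulatory lists did not pass the camera threshold with the filter on low counts and all 8 libraries. Of 23 glycolysis genes, 1 rose, Phka1 (2 higher and 1 lower adjusted over the list alone; list adjusted p = 0.306), and of 28 genes around the PGC-1 coactivators 2 rose, Sirt1 and Ppard (2 and 1; 0.604). The block gave 2 higher and 3 lower genes in each of these. Of 19 lipid storage genes, 1 rose, Me1, also an NRF2 target (3 higher adjusted over the list alone, 3 with the block; 0.213). Of 19 interferon-stimulated genes, 1 rose, Mx2 (1; 0.323), and of 15 clock genes 1 rose, Cry2 (2, and 2 with the block; 0.100). Of 25 hypoxia and 16 calcineurin genes, edgeR called 0 over all genes and over the list alone (2 and 2 at an unadjusted p under 0.05, 1 and 0 by DESeq2, 2 and 2 with the block; 0.517 and 0.891). Apart from Me1, which held without EPS replicate 1, each gene named here lost its call without control replicate 1, 3 or 4 or EPS replicate 1; Me1 lost it without control replicate 1, 3 or 4 (highest adjusted p 0.0555). The highest adjusted p of the others lay between 0.141 and 0.191. The glycolysis list passed its test, downwards, with no filter on low counts (adjusted p = 0.0413) and without control replicate 2 (0.00925), and the clock list, upwards, without control replicate 3 or EPS replicate 4 (0.0335 and 0.0379).

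Markers of dividing cells, other cell types and RNA quality moved as follows. Of 38 cell cycle genes, edgeR called 0 (4 higher at an unadjusted p under 0.05, 0 by DESeq2, 3 higher with the block), and the proliferation marker Mki67 had a log2 fold change of -0.32 (adjusted p = 0.621). Of 21 genes of undifferentiated myoblasts, 1 rose, Ccnd1 (cyclin D1; 1 higher and 1 lower adjusted over the list alone; 1 and 3 with the block). The 2 lists had medians of -0.29 and -0.25 and list adjusted p of 0.155 and 0.100, with the block 0.0346 and 0.0164, and with no filter on low counts 0.00515 and 0.00533. The cell cycle list also passed without control replicate 1 or 3 or EPS replicate 4 (adjusted p = 0.00816, 0.0318 and 0.00661), and the myoblast list without control replicate 2 (0.0385). Ccnd1 was past the threshold in only 1 of the 8 fits without a library (highest adjusted p 0.176). Extracellular matrix genes (28 tested) had a median of -0.34 and a list adjusted p of 0.0185, and 0.700 with an estimated correlation. By edgeR 0 were called (3 at an unadjusted p under 0.05, 2 by DESeq2; 1 higher and 8 lower with the block; 1 and 1 adjusted over the list alone). That list call was lost without control replicate 3 or 4 or EPS replicate 2 (adjusted p = 0.0593, 0.185 and 0.128). Of the osteoblast, adipocyte, macrophage and endothelial markers only 6, 4, 3 and 4 were tested, and edgeR called 0 (3 in all at an unadjusted p under 0.05, 0 by DESeq2, 3 with the block).

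Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had a median of -0.36 over 42 genes (list adjusted p = 0.0394, and 0.780 with an estimated correlation). EdgeR called 0 (1 at an unadjusted p under 0.05, 1 by DESeq2, 1 with the block). The list medians of the control libraries alone ran from -1.38 to 1.53, and the call was lost with size factors in place of TMM (adjusted p = 0.0507), with the stricter filter (0.0527) and without control replicate 3 or 4 or EPS replicate 1 or 2 (0.132, 0.630, 0.232 and 0.950). Ribosomal protein genes (62 tested, median -0.13, adjusted p = 0.100) and abundant non-coding RNAs (9 tested, median 0.65, adjusted p = 0.173) did not pass the list test with the filter on low counts and all 8 libraries, with 0 genes called by edgeR (3 in all at an unadjusted p under 0.05, 0 by DESeq2, 1 with the block). The ribosomal list passed, downwards, with no filter on low counts (adjusted p = 0.00231) and without control replicate 1 or 2 or EPS replicate 3 or 4 (adjusted p = 0.0351, 0.00499, 0.00232 and 0.00734). Non-coding RNA medians were 0.79 and 1.35 in EPS replicates 1 and 2, and between -0.41 and 0.34 in the other libraries.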

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

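The split test was written before its result was seen, and both tests of the heat shock pattern were chosen only after the result was seen. The 8 libraries can be parted into 4 and 4 in 35 ways, and only 1, the real one with 428 genes, gave as many genes past the threshold. The highest other split gave 181 (replicates 1 and 2 against 3 and 4), and among the 8 splits that part every replicate pair the highest other count by edgeR was 0 (6 to 569 genes at an unadjusted p under 0.05). Over all 35 splits an arbitrary grouping is excluded as the source of the count under the rule written beforehand. The replicate numbers pair the libraries in part, however, and the real split is 1 of only 8 that part all pairs. These are too few for a share under 0.05 in that comparison.

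Within groups of 4, 9 of 126 value sets had a library apart by Dixon's test. Chance gives about 1 in 20 where the 4 values have the same spread. The shallow control replicate 2 has more counting error than the others, so that rate need not hold for its values. Control replicate 2 had 11812 genes with a fragment (others 17482 to 18603). Its Hspa1b stood at 53.98 CPM (others 23.418 to 23.673), Trib3 at 0 (3.467 to 3.936), Me1 at 31.252 (16.966 to 18.635), Srxn1 at 5.682 (13.429 to 14.483) and Ppard at 5.682 (21.095 to 23.673). These 5 values rest on 19, 0, 11, 2 and 2 fragments. A count of 0 in that library allows up to 8.68 CPM, so counting error is not excluded as the source of the Trib3 value. That limit does not apply to Hspa1b, Me1, Srxn1 and Ppard, for which counting error was not tested. Its fast-fibre median was -0.266 (others 0.049 to 0.108). Ccnd1 stood at 90.023 CPM in EPS replicate 4 (71.991 to 72.290), and Cryab at 939.436 CPM in control replicate 1 (565.375 to 622.776).

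Heat shock genes spread more widely among EPS libraries (list medians 0.669 to 2.193) than among control libraries (-0.136 to 0.217). A scaling error could shift all lists alike, but the range of NRF2 targets was 12.73% of that of heat shock genes, which excludes it under the rule used. Transcript length and GC bias might widen the range, but offsets for both left it at 111.35% of its value before, which excludes it too. That the heat shock response itself differed in strength between cultures is a hypothesis that these libraries do not test. The labels do not say that the libraries came from separate cultures. A further check on sequencing depth was dropped after it had run, because it rested on 1 library.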

How the results depend on the processing

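The settings with library weights, robust dispersions, a batch term, parts of the replicates, the block without pair 2 and length and GC offsets were chosen only after the results were seen. Higher and lower genes numbered 322 and 106, against 633 and 294 with DESeq2, 130 and 48 with limma on log2(FPKM + 1), 94 and 29 with log2(FPKM + 0.1), and 205 and 59 against a 1.2-fold change. Lower genes were 162 with no filter and 288 with length and GC offsets. Pairing by the replicate block gave 1023 and 668, without pair 2 1290 and 1167, and with offsets 1219 and 994. Library weights gave 1262 and 962, the batch term 732 and 416, and replicates 3 and 4 only 1156 and 1121; replicates 1 and 2 only gave 510 higher. Leaving out 1 library gave 92 to 427 higher and 22 to 167 lower genes. Gdf15 was at 3.194 with log2(FPKM + 0.1) (adjusted p = 0.0545). Higher and lower lists were 6 and 12, against 1 and 0 with an estimated correlation, by camera. Fry, which tests a list against no change and not against other genes, gave 5 higher and 5 lower. By fry the immediate-early, respiratory chain, cholesterol and coupling lists were not past the threshold (adjusted p = 0.130, 0.244, 0.244 and 0.0659). The same held for structural sarcomere genes, genes held low by activity, extracellular matrix and histone genes (0.216, 0.149, 0.639 and 0.868). For all of these the cause was not tested. Of 55 named genes, 24 were no longer past the threshold with log2(FPKM + 0.1), 14 with log2(FPKM + 1) and 10 against a 1.2-fold change. Among the genes named in this text and the lists the block changed no call other than those of Hmgcs1, Myh3, p53 targets, cell cycle genes and genes of undifferentiated myoblasts.

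Directions turned only in results with no call; list values are the -log10 p of the list test with the sign of its direction. Calcineurin genes were at -0.4367 with no filter, -0.2136 with the block without pair 2, -0.2413 in replicates 3 and 4, -0.05743 with offsets, -0.1119 with block and offsets, and -0.1526 to 0.1642 without 1 library. Endoplasmic reticulum chaperones were at -0.04702 with no filter and -0.3644 in replicates 3 and 4. Lipid storage was at -0.002546 and -0.18, and osteoblast markers at -0.0645 and -0.06876, with the block without pair 2 and in replicates 3 and 4. By fry hypoxia was at 0.002388, secreted factors at 0.3382 and PGC-1 genes at 0.1178. Without 1 library hypoxia ran from -1.114 to 0.1643 and secreted factors from -0.2565 to 0.0466. Ribosomal genes were at 0.02534 with block and offsets, and Mki67 at a log2 fold change of 0.02991 with library weights. The cause was not tested.

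In replicates 1 and 2 alone the list calls of genes held low by activity, cholesterol synthesis, coupling, extracellular matrix and structural sarcomere genes were lost (adjusted p = 0.123, 0.0667, 0.0667, 0.0845 and 0.112), non-coding RNAs passed upwards (0.0313), and cell cycle and ribosomal genes passed downwards (0.00681 and 0.00881). In replicates 3 and 4 alone the histone call was lost (0.570), p53 targets passed upwards (0.0231), and glycolysis, hypoxia and undifferentiated myoblast genes passed downwards (0.0185, 0.0101 and 0.000515). The block without pair 2 also let glycolysis, hypoxia, myoblast and ribosomal genes pass downwards (0.00811, 0.0151, 0.00356 and 0.0488) and p53 targets upwards (0.0288). With the batch term p53 targets and myoblast genes passed (0.0162 and 0.0343), and with block and offsets these and cell cycle genes (0.0293, 0.0145 and 0.0429). Length and GC offsets ended the histone call without and with the block (0.109 and 0.0532). With the offsets alone 7 fast-fibre, 3 slow-fibre, 3 developmental, 7 structural, 4 coupling, 3 myogenic and 3 glycolysis genes were lower, and 3 structural and 2 glycolysis genes higher.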

Other observations

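All 6 lists in this paragraph, both tests of the respiratory chain pattern and the depth test of the detection pattern were chosen only after the results were seen, so the list p-values are not independent evidence. Of 8 tested genes controlled by the aryl hydrocarbon receptor, 7 rose (median log2 fold change 4.79, and 4.30 with 2 genes at their bound; adjusted p = 0.000739 with an estimated correlation). Among them were Cyp1b1 (2.04, SE 0.24) and Ahrr, the repressor of that receptor (4.25, SE 0.43). Of 17 glutathione transferases 7 rose, Gstm1 with 1.95 (SE 0.23), and of 32 proteasome subunits 6 rose and 31 had a positive fold change (adjusted p = 0.0403 and 0.0317 with an estimated correlation). Of 9 prostaglandin genes 5 rose, and of 6 metal response genes 2 rose, Slc30a1 and Hmox1 (0.0389 and 0.0279). These lists share called members with the fixed lists and are not separate from them. Hmox1 in the metal list, Nqo1 in the receptor list and Gsta4, Gstm1 and Gstp1 in the transferase list are NRF2 targets. Psmd11 in the proteasome list is also in the list of FoxO targets and autophagy genes. Ptgs2 in the prostaglandin list is an NF-kB target. Of 6 EGF receptor ligands 3 rose, and the list call was lost with an estimated correlation (adjusted p = 0.107). With the replicate block the proteasome count was 14 and the metal response count 4.

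Respiratory chain genes were lower on average in EPS, and technical causes may contribute. Their transcripts are short (median 1046 bases against 3220 for all), and offsets for length and GC left 64.52% of the median, from -0.31 to -0.20 (bootstrap interval -0.25 to -0.15), so this cause stays open. Pairs 1 and 2 had differences of -0.512 and -0.509, and pairs 3 and 4 of -0.123 (bootstrap interval over genes -0.147 to -0.094) and -0.142 (-0.177 to -0.109), with a list adjusted p of 6.39e-05 in replicates 3 and 4 alone at the preset correlation. Neither the intervals nor that p hold the spread that list members share within a library (estimated correlation 0.540 over all libraries), and the SD of 0.158 among control libraries also holds differences between pairs, so that pairs 1 and 2 alone carry the decrease stays open. The last criterion was tightened after the result was seen, and the first form had excluded this cause.

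EPS replicates 1 and 2 had fragments in more genes (20720 and 21698) than the other deep libraries (17482 to 18986). Depth is excluded, as the lower of the 2 still had 1529 more genes than any other after thinning. Genomic DNA might give such fragments. Silent genes were those with no fragments in control replicate 1, and folds are over control replicates 3 and 4 together, the other set of replicates. Far silent genes held 430 and 775 fragments in those 2 libraries. The fold of silent genes far from expressed genes was 0.425 and 0.311 of that just downstream on the same strand. This excludes genomic DNA as the sole source under the rule used. Transcription past gene ends could give this pattern, with the fold downstream at least 2.353 times that of far genes. This is the same ratio turned over, so it is no independent test, and far genes also rose 2.34- and 4.91-fold. Silent genes upstream rose 2.986- and 6.034-fold, and those downstream on the other strand 3.215- and 6.814-fold. Both rose more than far genes, so the pattern was not limited to genes downstream on the same strand.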
